A study of Homo sapiens with 6 samples.

How the data were processed

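RNA was measured in 143B cells, an established human osteosarcoma line. Per the labels' protocols, cells in 1 plate of 6 wells were grown for 24 h, 3 wells were set at random as controls and grown for a further 24 h, and celastrol, a triterpene from the root of Tripterygium wilfordii, was added to the other 3 wells for the same 24 h. The labels give no dose and do not say whether the control wells received a vehicle. Each library is 1 well, so the 3 replicates of a group are wells of 1 plate, and p-values measure the spread between these wells, which may be technical.

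Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads from 5 µg of total RNA with a RIN above 7. A strand-marking dUTP protocol with 8 PCR cycles gave inserts of about 300 bp, and both ends were read over 150 bp on a NovaSeq instrument. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with the build hg38. What each tool was used for is not given in the sources used here, nor are the annotation release, the counting settings and whether counting used the strand. The deposited count table holds whole-number read counts per gene, not normalized, for 22481 genes with their names and NCBI gene IDs. The deposited FPKM table was made by the authors from the same counts, scaled by gene length and by library total. In all 20198 genes with a count in at least 2 libraries, count and FPKM gave the same gene length in every library (within 1e-06 of its mean), so the FPKM values hold the same information as the counts and were used only as an alternative. Library totals ran from 38.4 to 39.5 M counts, at which a count of 0 allows up to 3 counts, or 0.076 to 0.078 CPM. Such limits cover counting error only, since the reads carry no molecular identifiers.

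From the counts, genes were kept with filterByExpr in edgeR 4.0.16 (15387 of 22481 genes) and scaled by TMM, and celastrol was compared with control by edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment (R 4.3.3). Adjusted p-values for single genes come from this test unless an alternative or a range over alternatives is named. A gene was called changed at an adjusted p under 0.05. Its standard error is the absolute log2 fold change divided by the square root of its F statistic. Group means are given in TMM-scaled CPM as mean ± SD with n = 3. Counts were simulated from these libraries with 200 changed genes, and 15195 genes were tested. The test recovered 26% of genes changed 1.25-fold, 68% at 1.5-fold, 84% at 2-fold and 92% at 4-fold, and 11 of its 146 calls (7.53%) were false. In the real comparison 48.4% of genes were called, so the adjusted threshold falls elsewhere and these rates may not hold there.

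The genes named were taken by a rule, and 3 genes that it takes are not printed: 9 genes of the pathways in the study's title whatever their result; the 6 largest log2 fold changes in each direction among called genes with a log2 CPM of at least 4, groups that do not overlap and a gene name rather than a clone or antisense name; 2 genes in the list's direction for each called list; and 4 in either direction for each of the 4 lists on the title's pathways, both with a log2 CPM of at least 2. Other members of a list are given only as examples of its counts and were chosen after their values were seen. The test, the named-gene rule, 30 gene lists and all alternatives except those named below as added were set before the data were examined. Lists with at least 5 tested genes (26 of 30) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 26 lists. Terms of KEGG, GO, WikiPathways and Reactome written in the deposited tables, with 10 to 500 tested genes each, were tested for enrichment by a one-sided Fisher's exact test against the 13230 tested genes that carry any term, for genes at least 2-fold higher and at least 2-fold lower. Single library values were compared by a two-sided exact permutation test, which with 3 wells against 3 cannot give a p under 0.1.

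Coordinates of named genes are those of RefSeq on GRCh38.p14, matched by NCBI gene ID (21761 of 22481 genes), a release of the assembly that hg38 names. Exons of 8 named genes share at least 10% of their bases with a gene on the opposite strand (PIK3CA, SQSTM1, BECN1, ATF5, PSMC5, NQO1, RPS25 and WIPI1). Their counts are uncertain by an amount that was not measured and that the share of bases alone does not set. KCNMB3, which overlaps PIK3CA, had a log2 CPM of -0.693, while NUP62, which overlaps ATF5, had 6.56. FTSJ3, which overlaps PSMC5, itself had a log2 fold change of 0.668. Ribosomal protein, ferritin, metallothionein, histone and mitochondrial genes have near-identical copies elsewhere in the genome, as do HSPA1A and HSPA1B, and how reads shared between copies were counted is not given in the sources used here. The alternatives were other scalings, filters and tools (DESeq2 1.42.0, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1), a test against a 1.5-fold change, a block by replicate number, other set tests, and leaving out each library in turn. Leaving out celastrol replicate 2 and control replicate 1 together, and counting the changed members of each list with libraries left out, were added after the data were seen. Intervals of medians are 95% bootstrap intervals from 2000 resamples of genes, and genes are not independent replicates.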

Results

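The data are 6 poly(A) RNA-seq libraries of 143B osteosarcoma cells, 3 from wells treated with celastrol for 24 h and 3 from control wells. Totals averaged 39.15 ± 0.286 M counts with celastrol and 38.89 ± 0.503 M in controls (SD, n = 3, two-sided exact permutation p = 0.4), and 18778 to 18948 genes were detected per library. The first principal component held 62.6% of the variance and separated the groups. Celastrol replicates 1, 2 and 3 scored -43, -35.3 and -45 on it, and control replicates 1, 2 and 3 scored 30.2, 48.5 and 44.6, so that celastrol replicate 2 and control replicate 1 lay nearest the other group. Within groups, every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 6.66 to 22.2), and each library was counted once.

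**Figure D1:**
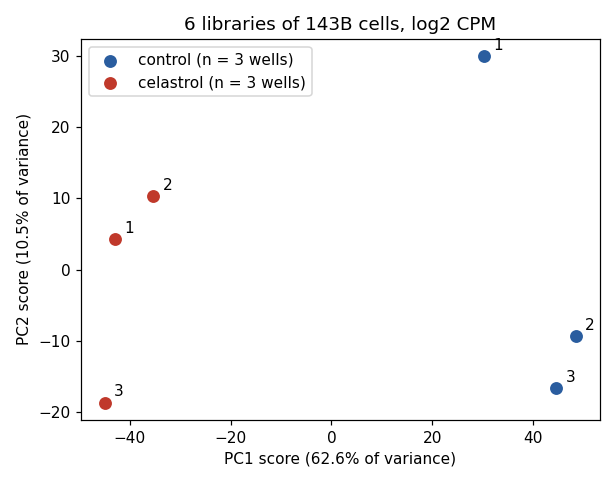
Scores of the 6 libraries on the first principal component (x axis, 62.6% of variance) and the second (y axis, 10.5%), computed from log2 CPM; each point is 1 well, numbered by replicate, red for celastrol and blue for control. The celastrol wells lie between -45 and -35.3 on the first component and the control wells between 30.2 and 48.5.

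The study's title names autophagy, apoptosis and PI3K/Akt/mTOR signalling, and the comparison of celastrol with control wells asks which transcripts differ after 24 h. The naming rule takes the largest changes among called genes with a log2 CPM of at least 4, and some less abundant genes changed by more. IL1B, an inflammatory cytokine (NCBI gene 3553, chromosome 2, 112829751 to 112836779), fell from 62.75 ± 23.2 to 2.397 ± 1.3 CPM (log2 fold change -4.71 ± 0.55 SE, adjusted p = 0.00266). THBD, the thrombin receptor thrombomodulin (gene 7056, chromosome 20, 23045633 to 23049672), fell from 57.99 ± 8.25 to 5.092 ± 1.16 CPM (-3.51 ± 0.15, adjusted p = 1.86e-10). ESM1, a proteoglycan (gene 11082, chromosome 5, 54977867 to 54985593), fell from 324.3 ± 41.6 to 30.57 ± 11 CPM (-3.41 ± 0.31, adjusted p = 0.00103). CHAC1, a glutathione-degrading enzyme (gene 79094, chromosome 15, 40953471 to 40956512), rose from 9.932 ± 2.56 to 53.56 ± 8.84 CPM (2.43 ± 0.18, adjusted p = 2.9e-06).

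Above that abundance, other large falls were in PLAT, tissue plasminogen activator (-3.32 ± 0.27, adjusted p = 0.000411), and BCL2A1, an anti-apoptotic protein (-2.71 ± 0.15, adjusted p = 4.38e-10). CD274, which encodes the immune checkpoint ligand PD-L1, fell as well (-2.70 ± 0.13, adjusted p = 1.86e-10). Among the largest rises at a log2 CPM of at least 4 were the WNT antagonist DKK1 (2.18 ± 0.33, adjusted p = 0.00516), the nuclear receptor coactivator NCOA5 (1.99 ± 0.19, adjusted p = 8.3e-05) and the transcription factor ATF5 (1.97 ± 0.14, adjusted p = 8.58e-09). The translation initiation factor EIF5 rose from 96.97 ± 31.1 to 363.3 ± 6.29 CPM (adjusted p = 0.00386), and the noncoding RNA LINC02806 from 17.02 ± 6.91 to 78.46 ± 17.3 CPM (adjusted p = 0.0083).

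Over all 15387 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3634 higher and 3815 lower with celastrol, 48.4% of genes. The balance turned with scaling, to 4170 higher and 3382 lower with library size alone and 4007 and 3257 by limma on log2(FPKM + 1). Of the genes called by edgeR with TMM, 505 were at least 2-fold higher and 931 at least 2-fold lower. The groups did not overlap in 56.9% of genes, against 10% by chance for 3 wells against 3. Without celastrol replicate 2 and control replicate 1, 3941 genes were higher and 4024 lower. Among genes with at least 10 CPM in at least 3 libraries, 145 were at least 2-fold higher and 311 at least 2-fold lower.

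**Figure D2:**
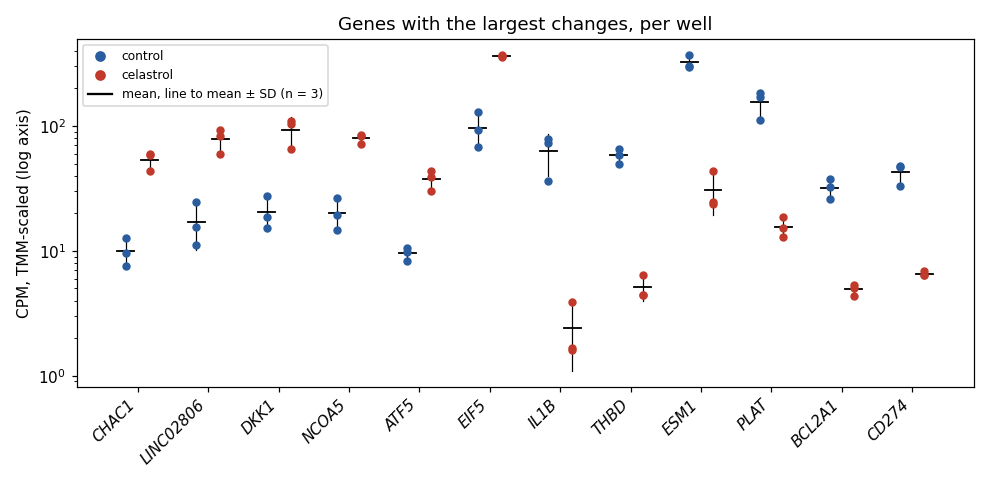
TMM-scaled CPM (y axis, log scale) of the 12 genes with the largest rises and falls at a log2 CPM of at least 4, taken by the naming rule, 1 point per well, blue for control and red for celastrol; bars mark the mean and lines the mean ± SD (n = 3). In all of them the wells of the 2 groups do not overlap, as for IL1B, at 62.75 CPM in controls and 2.397 CPM with celastrol.

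Genes of the PI3K, AKT and mTOR pathway went both ways. Of 32 tested, 9 rose and 12 fell (9 and 12 adjusted over the list alone), and as a set they did not pass the camera test (adjusted p = 0.311). The alternative set test fry, which does not compare a list with other genes, called the list lower (adjusted p = 0.0029). With library size alone, 11 genes were higher and 11 lower. PIK3CD, a catalytic subunit of PI3-kinase (gene 5293, chromosome 1, 9627258 to 9729114), fell from 109.7 ± 12.6 to 22.55 ± 2.54 CPM (-2.28 ± 0.098, adjusted p = 1.01e-10). The insulin receptor substrates IRS1 (-0.85 ± 0.073, adjusted p = 6.2e-08) and IRS2 (-0.78 ± 0.11, adjusted p = 3.03e-05) fell too. AKT1S1, which encodes the mTORC1 inhibitor PRAS40, rose (0.88 ± 0.089, adjusted p = 4.67e-07). MTOR rose from 143.8 ± 4.18 to 168.2 ± 2.39 CPM (0.23 ± 0.060, adjusted p = 0.00445) and AKT1 from 270.5 ± 11.3 to 306.4 ± 10.5 CPM (0.18 ± 0.058, adjusted p = 0.0157). PIK3CA stood at 38.29 ± 0.473 CPM in controls and 35.16 ± 3.49 with celastrol (adjusted p = 0.275). The AKT1 call was lost without celastrol replicate 1 (adjusted p = 0.0871), celastrol replicate 3 (0.0823) or control replicate 2 (0.0851), within a range of 0.00216 to 0.0871 over its 16 alternatives.

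Of 38 genes of the autophagy machinery, 9 rose and 12 fell (9 and 12 adjusted over the list alone), and the set did not pass the camera test (adjusted p = 0.536). By limma on log2 FPKM, 10 were higher and 9 lower. SQSTM1, the autophagy receptor p62 (gene 8878, chromosome 5, 179806393 to 179838078), rose from 320 ± 52.8 to 513.8 ± 60.7 CPM (0.68 ± 0.13, adjusted p = 0.00342). The receptor OPTN fell from 39.9 ± 5.87 to 11.99 ± 0.952 CPM (-1.73 ± 0.12, adjusted p = 5.15e-09). The phosphoinositide-binding WIPI1 fell by 0.60 on the log2 scale (SE 0.10, adjusted p = 0.000127) and the initiating kinase ULK2 fell by 0.55 (SE 0.12, adjusted p = 0.00138). MAP1LC3B, which encodes LC3B, had 110.7 ± 13.3 CPM in controls and 121.9 ± 8.12 with celastrol (adjusted p = 0.169). BECN1, a subunit of the autophagy-initiating lipid kinase complex, had 40.02 ± 2.07 and 44.36 ± 0.82 CPM (adjusted p = 0.14). MAP1LC3B passed only without control replicate 3 (adjusted p = 0.04999, range 0.04999 to 0.599 over 16 alternatives), and BECN1 only by limma on log2 FPKM (0.035 with a pseudocount of 1, range 0.035 to 0.361). Without control replicate 2, 5 autophagy genes were higher. Of 20 lysosome genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.304). Among them, TFEB, which encodes a transcription factor of lysosomal genes, was lower (-1.41).

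Among 23 pro-apoptotic genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone). The list was not called by camera (adjusted p = 0.263), but fry called it higher (adjusted p = 0.00063). The apoptosome component APAF1 (0.72 ± 0.096, adjusted p = 9.96e-06), the BH3-only gene BMF (0.69 ± 0.071, adjusted p = 4.82e-07) and the pore-forming BAX (0.37 ± 0.078, adjusted p = 0.000793) rose. BBC3, which encodes PUMA (-0.90 ± 0.13, adjusted p = 1.72e-05), and the initiator caspase gene CASP9 (-0.75 ± 0.14, adjusted p = 0.000281) fell.

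Of 10 anti-apoptotic genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone). The list was called lower by camera (adjusted p = 0.00442; adjusted p = 0.37 with an estimated correlation). MCL1 went from 1582 ± 137 to 826.9 ± 46.7 CPM (-0.94 ± 0.063, adjusted p = 5.55e-09) and BIRC3, a ubiquitin ligase of the IAP family, from 9.623 ± 1.45 to 0.7155 ± 0.414 CPM (-3.75 ± 0.29, adjusted p = 3.73e-08). The caspase-8 regulator CFLAR went from 97.88 ± 5.26 to 65.71 ± 5.24 CPM (adjusted p = 6.61e-06), and BCL2A1 belongs here too. BCL2 was at 13.22 ± 2.3 CPM in controls and 11.88 ± 0.884 with celastrol (adjusted p = 0.387). The list's call was lost with at least 10 CPM required in 3 libraries (camera adjusted p = 0.0759) and on log2(FPKM + 1) (0.214), in a range of 0.000142 to 0.214 over 13 alternatives.

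**Figure D3:**
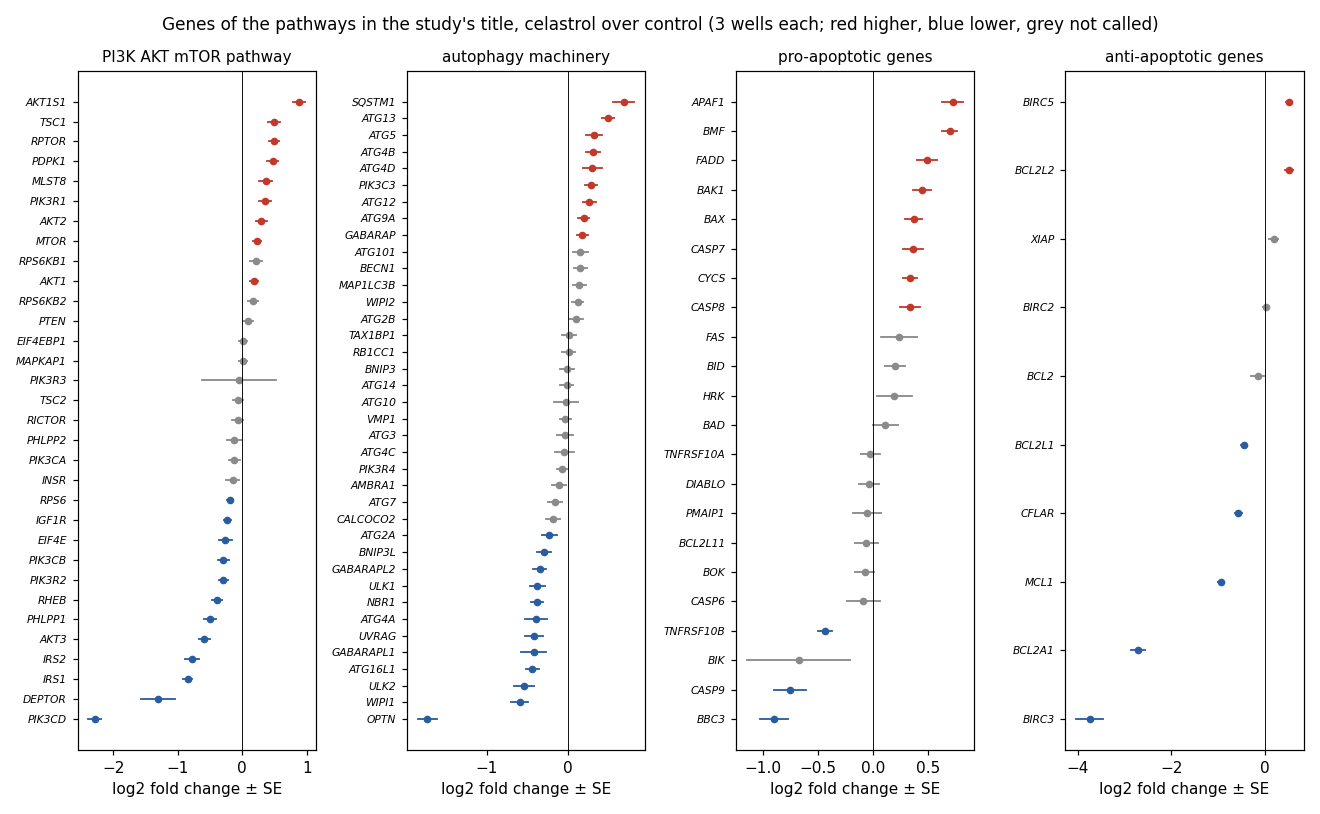
Log2 fold changes (x axis, celastrol over control, ± SE, 3 wells each) of all but 1 of the tested genes in the 4 lists on the pathways of the study's title, 1 row per gene on the y axis; red genes were called higher, blue lower and grey not called. In the PI3K, AKT and mTOR list 9 genes rose and 12 fell, from AKT1S1 at 0.88 to PIK3CD at -2.28.

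Of 22 targets of the amino acid stress factor ATF4, 16 rose and 2 fell (16 and 2 adjusted over the list alone). The list was called higher (camera adjusted p = 1.19e-08; adjusted p = 0.37 with an estimated correlation). NUPR1 had 61, 24 and 62 counts in celastrol replicates 1, 2 and 3 and 1, 7 and 0 in control replicates 1, 2 and 3, too few in controls for an exact fold. The stress cytokine GDF15 rose from 1.611 ± 0.452 to 10.91 ± 2 CPM (2.76 ± 0.22, adjusted p = 2.46e-08), and CHAC1 belongs here too. The members that fell were VLDLR (-0.17) and ASNS (-0.77). ASNS was read at only 82 to 205 counts per library and overlaps the annotated readthrough CZ1P-ASNS, so its value is uncertain. Without control replicate 2 or 3 or any 1 celastrol replicate, 1 member was lower. Of 20 NRF2 targets, which encode antioxidant and related enzymes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.49 with an estimated correlation). The cystine carrier gene SLC7A11 (1.56 ± 0.10, adjusted p = 1.36e-08) and the quinone reductase gene NQO1 (1.34 ± 0.078, adjusted p = 1.01e-09) rose, while HMOX1 did not pass the test (0.17, adjusted p = 0.545). Without celastrol replicate 1 or 3 or control replicate 2 or 3, 1 NRF2 target was lower.

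Of 31 proteasome subunits, 21 rose and 2 fell (21 and 2 adjusted over the list alone). The ATPase subunit genes PSMC3 (0.54 ± 0.062, adjusted p = 1.58e-06) and PSMC5 (0.44 ± 0.061, adjusted p = 1.25e-05) were among them. The list was called higher (camera adjusted p = 0.000677; adjusted p = 0.41 with an estimated correlation), and 1 member was lower without celastrol replicate 1 or 3. Heat shock chaperones were not called as a list (camera adjusted p = 0.254), with 6 of 24 higher and 0 lower by edgeR (5 and 0 adjusted over the list alone; 0 lower at an unadjusted p under 0.05, 1 by DESeq2 and 2 by limma-voom). The 6 included the collagen chaperone gene SERPINH1 (0.71) and HSPA8 (0.45). HSPA1A, a stress-induced HSP70 gene with a near-identical copy, had 13.3 to 14.9 CPM in the celastrol wells and 13.5, 15 and 44.3 CPM in control replicates 1, 2 and 3 (adjusted p = 0.331). The copy, HSPA1B, had 23.7 to 27.9 CPM in the celastrol wells and 36.9, 39.8 and 85.1 CPM in these controls. It was lower in every celastrol well but was not called by edgeR. Without control replicate 1, 3 chaperones were lower, and without control replicate 3, 1 was.

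Genes of ER chaperones and ER-associated degradation went both ways, 4 higher and 6 lower of 22 (4 and 6 adjusted over the list alone; camera adjusted p = 0.964). Their median of -0.0065 and mean of -0.051 differed in sign from the direction of camera, and the median was 0.035 with library size alone. By limma on log2(FPKM + 1), 6 were higher and 6 lower. Of 6 metallothionein and metal transport genes, MT1F (1.76), MT1M (1.47) and MT1E (1.24) rose and MT2A (-0.63) fell (3 and 1 adjusted over the list alone). Camera called this list only without celastrol replicate 2 (adjusted p = 0.0124, against 0.237 with all libraries and a range of 0.0124 to 0.581 over 12 alternatives).

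DNA replication genes rose, 22 of 26 with 0 lower by edgeR (22 and 0 adjusted over the list alone; 0 lower at an unadjusted p under 0.05 and by DESeq2 or limma-voom; camera adjusted p = 6.03e-10; adjusted p = 0.26 with an estimated correlation). The helicase factor gene CDC45 went from 31.83 ± 4.35 to 54.41 ± 2.69 CPM (0.77 ± 0.096, adjusted p = 3.89e-06). Without control replicate 1, 1 of these genes was lower. Mitosis genes were not called as a list, with 5 higher and 10 lower of 25 (6 and 10 adjusted over the list alone; camera adjusted p = 0.353). The balance turned with scaling, to 7 higher and 5 lower with library size alone, and to 5 and 4 or 6 and 4 by limma on log2 FPKM with a pseudocount of 1 or 0.1. The anaphase ubiquitin-conjugating enzyme gene UBE2C fell (-0.51), and the checkpoint kinase gene BUB1B rose (0.24). Mitosis genes higher and lower were 4 and 5, 2 and 5, and 2 and 8 without celastrol replicates 1, 2 and 3, and 3 and 14, 3 and 4, and 2 and 5 without control replicates 1, 2 and 3. Of 11 replication-dependent histone genes, 3 rose, among them H2AC6 (1.10), and H1-2 (-1.06) fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.536).

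Ribosome biogenesis genes rose, 15 of 24 with 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.000142; adjusted p = 0.41 with an estimated correlation). The snoRNP protein gene NOP58 (0.82 ± 0.069, adjusted p = 4.15e-08) and POLR1A, the large subunit of RNA polymerase I (0.67 ± 0.069, adjusted p = 4.82e-07), were among them, and the member that fell was the transcription factor gene MYC (-1.22). Without control replicate 1, 2 were lower. Ribosomal protein genes fell, 20 of 36 with 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 0.0198; adjusted p = 0.75 with an estimated correlation). RPS25 was at -0.29 ± 0.062 (adjusted p = 0.000886) and RPL3 at -0.27 ± 0.052 (adjusted p = 0.000319). That list's call was lost without celastrol replicate 2 (camera adjusted p = 0.0535, 13 lower), control replicate 3 (0.0744) or celastrol replicate 2 with control replicate 1 (0.0564), in a range of 0.0016 to 0.0744 over 13 alternatives.

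Of the 13 mitochondrially encoded genes, 9 fell and 0 rose by edgeR (10 and 1 adjusted over the list alone; 1 higher at an unadjusted p under 0.05 and by DESeq2 or limma-voom; camera adjusted p = 2.33e-05; adjusted p = 0.25 with an estimated correlation). CYTB, a subunit of respiratory complex III, went from 4444 ± 322 to 2379 ± 45.7 CPM (-0.90 ± 0.054, adjusted p = 1.26e-09) and ND2, of complex I, from 4107 ± 323 to 2291 ± 46 CPM (-0.84 ± 0.055, adjusted p = 3.44e-09). COX1 was at -0.0015 (adjusted p = 0.982), and ND6, encoded on the opposite strand to the others, at 0.83 (adjusted p = 0.0663). Without control replicate 1, 1 was higher. Together the 13 genes took 4.563% ± 0.108 of counts with celastrol and 5.665% ± 0.165 in controls (SD, n = 3, two-sided exact permutation p = 0.1, the smallest 3 against 3 allows). Of 27 nuclear respiratory chain genes, 4 were higher and 4 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.974). Their median of -0.011 differed in sign from their mean of 0.000251 and from camera's direction, and was 0.030 with library size alone, where 6 were higher and 2 lower (5 and 2 by limma on log2 FPKM). Without celastrol replicates 1, 2 and 3, the nuclear genes higher and lower were 2 and 2, 4 and 2, and 2 and 2.

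Cholesterol synthesis genes fell as a list, 13 lower and 5 higher of 22 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00404; adjusted p = 0.41 with an estimated correlation). INSIG1, which encodes an ER protein that restrains SREBP processing, went from 130.9 ± 28.6 to 65.21 ± 3.57 CPM (-1.01 ± 0.13, adjusted p = 0.00019) and the sterol demethylating oxidase gene MSMO1 from 90.45 ± 5.07 to 49.3 ± 10.7 CPM (-0.88 ± 0.13, adjusted p = 0.000228). MSMO1 did not pass without both celastrol replicate 2 and control replicate 1 (adjusted p = 0.0753, range 1.41e-25 to 0.0753 over 16 alternatives). The members higher were 1 and 3 without celastrol replicates 1 and 3, and 3 and 2 without control replicates 2 and 3. Glycolysis and hypoxia genes were 5 higher and 6 lower of 21 (5 and 6 adjusted over the list alone; camera adjusted p = 0.536), from ADM at 1.24 to NDRG1 at -1.14, and 6 higher and 5 lower with library size alone. Without control replicate 1, 8 were higher. Targets of p53 were 3 higher and 7 lower of 15 (3 and 7 adjusted over the list alone) and were not called by camera (adjusted p = 0.0833). Fry called them lower (adjusted p = 0.0076). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell (-0.77, adjusted p = 9.08e-08). The p53 list was called lower without celastrol replicate 1 (camera adjusted p = 0.0465), without control replicate 1 (0.0286) and with no filter on low counts (0.0278), in a range of 0.0278 to 0.135 over 13 alternatives. Without celastrol replicate 2 or 3, 1 p53 target was higher.

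Of 18 NF-kB targets, 9 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 3.33e-05; adjusted p = 0.41 with an estimated correlation). TNFAIP3, which encodes a feedback inhibitor of NF-kB, went from 26.34 ± 8.79 to 2.685 ± 0.464 CPM (-3.29 ± 0.27, adjusted p = 6.53e-06), and BIRC3 belongs here too. The chemokine gene CXCL8 was at 0.80 (adjusted p = 0.072), and the member that rose was IRF1 (0.33). Of 20 AP-1 and immediate early genes, 14 fell and 1, JUND (0.33), rose (15 and 1 adjusted over the list alone; camera adjusted p = 6.03e-10; adjusted p = 0.25 with an estimated correlation). The MAP kinase phosphatase gene DUSP1 went from 186.1 ± 27.4 to 34.14 ± 2.43 CPM (-2.45 ± 0.098, adjusted p = 1.24e-10) and the transcription factor gene EGR1 from 300.9 ± 93.6 to 62.96 ± 5.38 CPM (-2.26 ± 0.26, adjusted p = 0.00206). By edgeR, 0 NF-kB targets were higher without celastrol replicate 1 or 3, and 0 immediate early genes without celastrol replicate 1 or control replicate 3, against 2 without control replicate 1. Interferon response genes were 1 higher and 6 lower of 18 (1 and 4 adjusted over the list alone; camera adjusted p = 0.311), with OASL at -2.82. Without celastrol replicate 3, 2 interferon genes were higher and 3 lower, and without control replicate 2, 3 were lower.

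Of 20 migration and matrix protease genes, 14 fell and 5 rose (14 and 5 adjusted over the list alone; camera adjusted p = 0.000453; adjusted p = 0.37 with an estimated correlation). The membrane protease gene MMP14 went from 527.5 ± 47.7 to 219 ± 33.8 CPM (-1.27 ± 0.11, adjusted p = 4.25e-06). The secreted protease gene MMP3 rose instead, from 0.6334 ± 0.299 to 12.30 ± 0.990 CPM (4.27 ± 0.26, adjusted p = 1.81e-09). Without control replicate 2 or any 1 celastrol replicate, 3 members were higher. Of 15 extracellular matrix and osteoblast genes, 9 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0297; adjusted p = 0.37 with an estimated correlation). The matrix protein gene TNC was at -1.01 ± 0.074 (adjusted p = 1.22e-08), the osteoblast transcription factor gene RUNX2 at -0.90 ± 0.10 (adjusted p = 1.15e-06) and the collagen gene COL1A1 at 0.66 (adjusted p = 0.00209). The call of the matrix and osteoblast list was lost without celastrol replicate 2 (camera adjusted p = 0.0535), with at least 10 CPM required in 3 libraries (0.0642) and on log2(FPKM + 1) (0.0502), in a range of 0.00602 to 0.0642 over 13 alternatives.

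Camera called 5 lists higher and 8 lower of the 26 tested. With an estimated correlation camera called 0 and gave an unadjusted p under 0.05 for 3, the DNA replication, mitochondrially encoded and AP-1 lists. Fry, which does not compare a list with other genes, called 16. The lists called by fry but not by camera were the PI3K, AKT and mTOR, pro-apoptotic and p53 lists. Other splits of the 6 libraries into 3 and 3 gave up to 9 called lists in 1 direction. Those splits mix the treatments but keep part of the treatment difference, so this is not a count expected by chance. Markers of other cell types were mostly under the filter: 3 of 10 were tested for epithelial cells, 2 of 10 for blood and immune cells, 1 of 6 for endothelial cells and 2 of 10 for neural and liver cells. The epithelial genes CDH3 (1, 1 and 0 counts with celastrol, 17, 15 and 16 in controls) and CLDN4 (-1.57) and the endothelial receptor gene KDR (-1.40) were lower, and the myeloid factor gene SPI1 (2.01) was higher (2 epithelial, 1 endothelial, 2 blood and 0 neural and liver genes adjusted over the list alone). No neural or liver marker was called by edgeR, at an unadjusted p under 0.05 or by DESeq2 (0 each). CDH3 averaged 0.4174 CPM in controls, CLDN4 1.08, KDR 1.089 and SPI1 0.3049. The KDR call was lost without celastrol replicate 2 or 3 or control replicate 2, and without that control 1 epithelial marker was lower and 2 blood markers were higher.

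**Figure D4:**
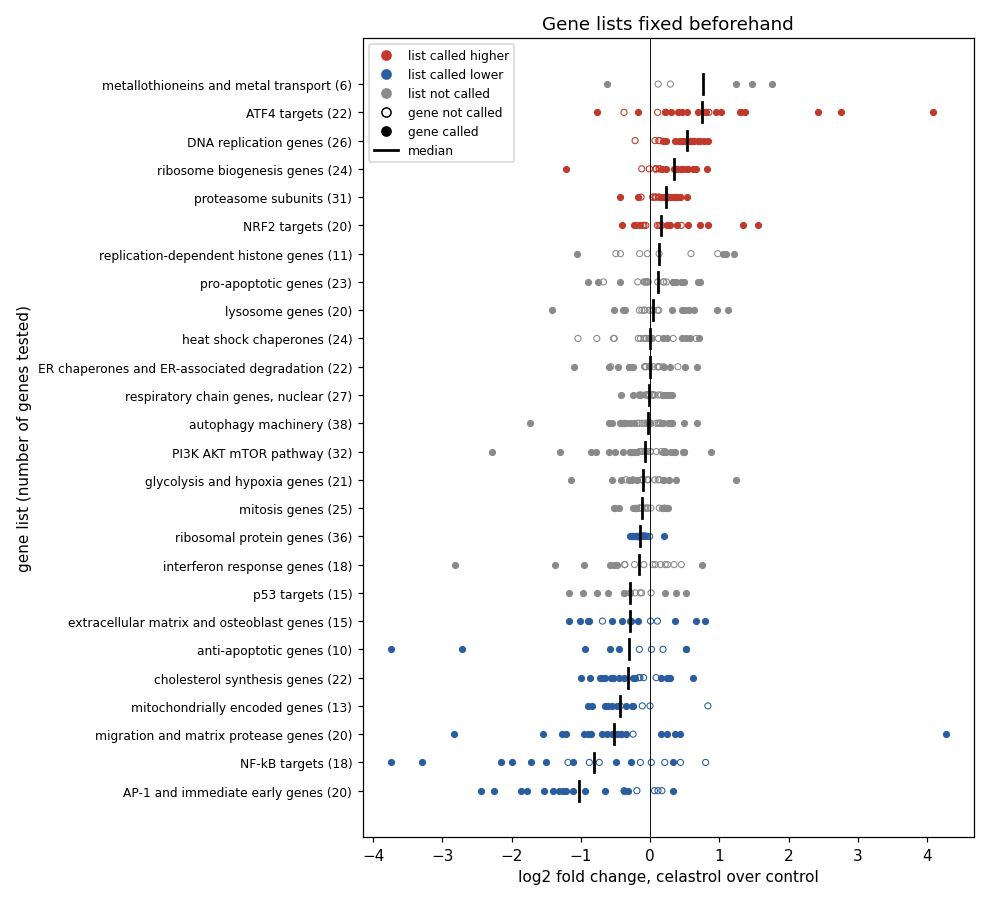
Log2 fold changes (x axis, celastrol over control) of the members of the 26 gene lists tested (y axis, with the number of genes tested); filled points passed the test, open points did not, black bars are medians, and red and blue lists were called higher and lower by camera. The AP-1 and immediate early list has 14 members lower and 1 higher, and the DNA replication list 22 higher and 0 lower.

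Of the annotation terms, 149 were enriched among genes at least 2-fold lower. Among these were cell surface (60 genes against 20.14 expected, adjusted p = 9.17e-11), extracellular matrix (32 against 7.737, adjusted p = 1.11e-08), cell adhesion (42 against 14.38, adjusted p = 5.7e-07) and cytokine activity (22 against 4.61, adjusted p = 7.08e-07). These come from a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 5665 terms. Among genes at least 2-fold higher, 2 terms were enriched. Amino acid transmembrane transport held 5 of its 14 genes against 0.3503 expected (adjusted p = 0.0448), namely SLC7A11, SLC38A1, SLC38A9, SLC38A2 and SLC7A5. The KEGG term for herpes simplex virus 1 infection held 29 of 382 against 9.557 expected (adjusted p = 0.000593), and 27 of the 29 were zinc finger genes, such as ZNF780B (1.54 ± 0.15, adjusted p = 3.1e-07) and ZNF480 (1.36 ± 0.14, adjusted p = 3.34e-07). With all called genes whatever their fold, 302 terms were enriched among higher and 511 among lower genes. Those among higher genes were led by the Reactome terms G1/S Transition (78 of 130 genes against 32.71 expected) and S Phase (90 of 160 against 40.26), each with an adjusted p of 1.1e-13. Further down were M Phase (144 of 368 genes against 92.6 expected, adjusted p = 5.81e-07) and Mitotic Anaphase (101 of 226 against 56.87, adjusted p = 4.73e-08). The fixed list of mitosis genes, by contrast, had 5 higher and 10 lower of 25 and was not called (camera adjusted p = 0.353). Which genes these terms share with each other, or with lists such as the proteasome subunits, was not examined. The terms therefore do not show that mitosis genes as such rose.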

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

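Leaving out celastrol replicate 2 with control replicate 1, and counting each list's changed members without single libraries, were tests chosen only after the data were seen. Requiring at least 10 CPM in at least 3 libraries left fewer genes to test and gave 145 genes at least 2-fold higher and 311 at least 2-fold lower. Limma on log2(FPKM + 1), a scale that understates the change of low genes, gave 119 and 181, and a test against a 1.5-fold change gave 319 genes at least 2-fold higher; the causes were not tested. Camera with an estimated correlation called 0 lists higher and 0 lower, with 3 lists at an unadjusted p under 0.05, against 16 by fry. Taking all called genes whatever their fold gave 813 enriched terms in place of 151. With 1 library left out, which also lowers the number of samples, genes higher ranged from 2932 to 4043, genes lower from 3145 to 4067, genes at least 2-fold higher from 441 to 701, genes at least 2-fold lower from 779 to 998, lists higher from 5 to 6 and lists lower from 6 to 9. In every alternative with a fit over all genes, the genes also called in the full analysis kept their direction. With 1 library left out, 5993 to 7064 of the 7449 genes called in the full analysis were called again. Of 910 values for the 57 named genes under the alternatives, 901 kept their direction and side of the threshold, 5 newly passed it, 4 no longer did and 0 reversed direction. Apart from the 9 genes named whatever their result, these were taken for being called with large changes in the same libraries. Their high share kept is therefore largely built in and does not describe called genes in general. Depth limits genes near 3 counts, 0.076 to 0.078 CPM, below which a gene is not told from one at 0.

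The labels number the wells 1 to 3 in each group. The correlations of deviations from the group means were 0.058, 0.055 and 0.034 for same-numbered pairs, none over the 0.1 taken as a mark of pairing. For pairs with different numbers they were at most 0.0053, and all 6 libraries correlated best with their own number. Whether the numbers pair the wells therefore stays open. With the number as a block, 3831 genes were higher, 3928 lower, 514 at least 2-fold higher and 916 at least 2-fold lower, with 5 lists higher and 8 lower.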

Other observations

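The gene families, the zinc finger tests and the mixing tests were chosen only after the results were seen. Of 19 amino acid carrier genes, 15 rose and 2 fell (two-sided Fisher's exact adjusted p = 6.67e-06 for higher genes), including the glycine carrier gene SLC6A9 (1.82) and the glutamine carrier gene SLC38A1 (1.35). This set joins the SLC7A and SLC38A genes with SLC6A9, SLC3A2, SLC1A4 and SLC1A5, which were added singly. Each gene added singly rose, so the p-value is not independent of the values. Of 17 cytosolic tRNA synthetase genes, 12 rose and 2 fell (adjusted p = 0.000325), with AARS1 at 0.54. Of 20 genes taken by integrin symbols, 13 fell and 2 rose (adjusted p = 0.000664 for lower genes), with ITGB3 at -2.24 and ITGA5 at -1.21. They include the integrin-like gene ITGBL1, which is not an integrin subunit and was not called (0.0036). Of 12 SR splicing factor genes, 7 rose and 2 fell (adjusted p = 0.0247), with SRSF3 at 0.78. Of 21 heterogeneous nuclear ribonucleoprotein genes 10 rose and 0 fell by edgeR (adjusted p = 0.0346; 0 lower at an unadjusted p under 0.05 and by DESeq2). Of 19 dual specificity phosphatase genes, 7 fell and 1 rose (adjusted p = 0.31). Adjustment covers both directions of these 6 families, whose genes are not independent, and each family's median had 1 sign under TMM, DESeq2 size factors and library size alone.

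Single genes chosen after their values were seen follow. MEPCE and HEXIM1, both of the 7SK complex that restrains transcription elongation, rose by 1.43 (adjusted p = 3.52e-08) and 0.82 (adjusted p = 1.28e-06). Control replicate 3 held more counts of some heat shock genes than control replicates 1 and 2, with 1706 against 519 and 568 for HSPA1A and 8415 against 4074 and 4920 for DNAJB1. That well also held more counts of the ER chaperone gene HSPA5 (45748 against 24678 and 34979) and of DDIT3, a member of the ATF4 list (1021 against 478 and 526). Whether the heat shock, ER or ATF4 list as a whole differed in that well was not tested.

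Zinc finger genes of the herpes simplex term were higher as a group, 99 higher and 13 lower of 244, with a median of 0.36 (95% interval 0.28 to 0.453) against -0.0052 in other coding genes. After regression on GC content, length and expression level, their median was 0.444 (0.367 to 0.543), which argues against that trend as the whole cause. Their summed CPM was higher in every celastrol library (2660 to 2852) than in every control (2251 to 2290), a log2 ratio of 0.292. Reads redistributed among these 244 genes alone would leave the sum in place. Zinc finger genes outside the term or under the filter were not summed, so reads gained from them could also raise it. The higher counts were measured, but no test of a biological cause was made, so such a cause remains a hypothesis. How reads shared between family members were counted stays open.

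Control replicate 1 and celastrol replicate 2 lay nearest the other group, and RNA of the other group mixed into the library could cause this. Mixing would give 1 share from higher and lower genes, but for control replicate 1 the shares were 17.8% (15.5 to 20.1) and 25.1% (21.1 to 28.6), a gap of -7.37 points, and for celastrol replicate 2 they were 15% and 7.07%, a gap of 7.89. The intervals of the 2 shares did not overlap in either library, which met the rule written against mixing, a rule itself written after the result was seen. A comparison with the other libraries was then added: each library scored on genes chosen without it gave gaps of -9 and 9.07 for these 2 and up to 7.89 in size for the other 4. The other 4 were scored against group means that include these 2 libraries, so their gaps are not an independent baseline. With a margin of 1.5 times that largest gap, also added afterwards, the gaps of -7.37 and 7.89 do not decide, but the margin rests on that baseline. Mixing or a different response of the well could each account for the pattern.

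The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3634 genes higher and 3815 lower, 505 and 931 at least 2-fold, and the highest other value by edgeR was 0 for each of these 4 counts, so that 1 split in 10 was as large. At an unadjusted p under 0.05 the real split gave 4146 and 4299 genes and the highest other 157. Every other split puts wells of both treatments in each group, so the treatment difference widens the spread within groups and lowers these counts. The values of 0 and 157 are therefore not what groups without any treatment difference would give. For lists, the real split was compared with the larger direction of each other split. Counted so, 5 splits, the real one included, gave at least the real 5 higher (highest other 9) and 4 at least the real 8 lower (highest other 9). Each other split still has more celastrol wells on 1 side, so it keeps part of the treatment difference. Its list counts are therefore not what groups without any treatment difference would give, and the comparison does not decide whether the list calls arise by chance.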
